A study of Danio rerio with 4 samples.

How the data were processed

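Gene expression was measured on 2-colour arrays in zebrafish eyes with the optic nerve severed, in sham-operated eyes and in eyes of unoperated fish. Each array held 14784 spots in 32 blocks: 14067 zebrafish oligonucleotide probes, 173 Arabidopsis control probes and 544 empty positions. Per the labels' protocols, total RNA was pooled from several wild-type fish for each sample, its quality was checked by spectrophotometry, gel and BioAnalyzer, and amplified RNA carrying amino-allyl groups was coupled to Cy3 or Cy5. The deposited scanner files give, per the file headers, the foreground and local background intensity of every spot in the Cy5 and the Cy3 channel, and these intensity values had not been normalised. A further deposited table holds 1 log2 value per spot and time point, which the authors computed from the same arrays, and the submitters' processing notes name limma with no version. Other steps the authors took are unknown here.

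Samples were grouped by the labels into injured against sham at 3, 24 and 168 h, with 3 arrays each, and unoperated control against control, with 2 arrays that share 1 control pool although the labels speak of 4 control samples. The labels call the arrays of a time point biological replicates, so each is a separate pair of pools. The dye of each pool had to be settled first. The labels put injured RNA in Cy5 throughout, whereas the names of the arrays put sham RNA in Cy5 on 6 of the 9 arrays and injured RNA in Cy5 on 3 of them, 1 at each time. The authors' value table decided between these readings: its columns correlated with the oriented mean log ratios of the array names at r = 0.873 (3 h), 0.894 (24 h) and 0.884 (168 h) across probes, and with the plain Cy5 over Cy3 means at r = -0.452, -0.497 and -0.406. Probes are not independent replicates, and these values describe only which reading the authors followed. All signs below are injured over sham in that orientation.

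In the comparison with the authors' log2 table, least-squares weights of the 3 arrays of a time point lay close to each other in size, between 0.285 and 0.300, with the signs of the array names. The table holds 14240 lines, of which the zebrafish probes with a ratio on all 3 arrays of a time point were compared. Of these, 84.7%, 81.2% and 83.5% lay within 0.02 of the plain mean of the oriented log2 ratios at 3, 24 and 168 h. That mean was taken without background subtraction and without a dye term, and 9.83%, 10.0% and 10.4% lay more than 0.1 away from it. The column medians were 0.01 at 3 h, 0.00 at 24 h, 0.01 at 168 h and -0.12 for the controls. Direction and scale of the 3 injured columns follow from this comparison, whereas any centring the authors applied and the origin of the control column stay unknown.

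Foreground mean and background median were read with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50 on all spots, and log2 ratios were normalised by loess within each array with weight 0 for control spots, empty positions and spots marked bad by the scanner (0 to 4 spots per array), with no scaling between arrays. The 9 injured-against-sham arrays were fitted together for each probe with 1 injury coefficient per time point, entered as plus or minus by dye orientation, and 1 dye effect common to all arrays. This left 5 residual degrees of freedom, to which limma's empirical Bayes step added 9.99, and the median standard error was 0.339 for a time point and 0.203 for the average over times. Probes were tested with limma's moderated test and Benjamini-Hochberg adjustment at 0.05, for each time, for the average, for any time (F test) and for the differences between times. With no effect, a share of 0.05 of the probes is expected at an unadjusted p under 0.05. The control arrays stayed outside the fit, since they held neither injured nor sham RNA. P-values of single probes rest on the spread between pools of fish, and the number of arrays limits their precision.

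A spot counted as detected in a channel when its foreground exceeded the 95th percentile of the empty positions of that array. No fold is given for a gene with no detected spot on 1 side of a comparison or on both. More spots were detected in Cy3 than in Cy5, so detection on 1 side alone is confounded with dye and does not show presence on that side only.

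Probes were named through their accessions: 7755 matched a RefSeq gene record of the GRCz12tu assembly, which was used only for names. A further 170 kept a current symbol from the files, 458 carried an older symbol that was updated, 145 kept the name of the file and 5539 had no symbol, and the array's names can be old. With provisional symbols such as clone and locus labels left out, 8297 probes had a gene name, covering 5089 genes, of which 1801 had several probes. The list tests used genes with a symbol of either kind. A gene with several probes is represented by the one with the highest mean intensity over all arrays, and other probes are mentioned where their sign differs. Other probes are given whether detected or not, and the sign of an undetected probe carries little information.

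There were 28 gene lists, written with the grouping, the tests and the alternatives before the data were examined: axon regeneration, immediate early, JAK-STAT and IL-6 family, heat shock and chaperone, unfolded protein and oxidative stress, complement and acute phase, cytokine and innate response, leukocyte and microglia, erythrocyte, skeletal muscle, lens, retinal pigment epithelium, rod, cone, retinal ganglion cell, inner retinal neuron, Müller glia and astrocyte, cell cycle, cytoskeleton and axonal transport, extracellular matrix, epithelial and corneal, apoptosis and p53, hypoxia and glycolysis, circadian clock, sterol and lipid, ribosomal protein, proteasome and oxidative phosphorylation genes. Some genes stand in more than 1 list, such as atf3, tubb5 and apoeb. Genes with a spot marked bad on any array were left out of the list tests. Shifts were tested with limma's camera over 5245 genes with its preset correlation, adjusted over all 112 tests of lists at the 3 times and on average, and separately over 84 tests of differences between times. The same tests were run with an estimated correlation between genes and with fry. Single members were also adjusted within their list and contrast alone, with no correction over the lists and contrasts. A pass over the list alone is therefore weaker than one over all probes, and some are to be expected by chance.

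Named genes followed a rule. For each time and the average these were up to 6 genes with the largest log2 change in each direction that passed the test with 1 sign on all 3 arrays (8 of 9 for the average), filled to 3 by the smallest p of that sign and then said not to have passed. To these came up to 4 members of each list whose shift is reported, and a fixed set of regeneration, glial and retinal genes whatever their values. Of that set tuba1a, tuba1c, klf7b, socs3b, hsp70l, nefma and hmox1a had no probe under those names. A few genes that the rule took are not described here. For a difference between time points the rule took genes that passed, and there were 0.

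The pipeline was tested on simulated arrays. For the 168 h comparison over 14067 probes, of 50 probes changed by a log2 value of 1 it recovered 22%, by 2 it recovered 98%, and by 3 or 4 it recovered 100%, with 16 other probes called. No probe was called at 3 h or 24 h, where none had been changed. Many probes were changed at once, which eases the adjusted threshold, and noise was independent between probes. These shares therefore do not carry over to the real arrays. There tubb5 at 2.31 (168 h) had an adjusted p of 0.0683 in limma, and atf3 at 2.01 (24 h) one of 0.265. A list shift of 0.4 came back as 0.41, and of 110 other list tests, where nothing had been shifted, 1 was called. A list of 71 unchanged genes with a correlation of 0.3 among them passed an unadjusted p of 0.05 in 59% of 100 draws with camera's preset correlation, and in 4% with an estimated one. The preset test is therefore too liberal for lists whose members vary together between pools, and the correlation estimated here was 0.318 for ribosomal protein, 0.283 for rod, 0.153 for lens, 0.142 for epithelial and 0.134 for cone genes.

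Alternatives covered the background method and offset, median centring, print-tip loess, Aquantile scaling, array weights, all spots kept, the brighter probes alone, the mean of all probes of a gene, no dye term, each time alone, the control arrays added, Cy5 taken as injured on every array, the threshold, the authors' table, camera with an estimated correlation, fry, and each array left out in turn. Foreground medians and the joint omission of 2 arrays were added after seeing the data. No scan date or slide number was found in the files, so a batch term was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.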

Results

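The series followed the zebrafish eye after the optic nerve was severed, an injury from which fish regrow the axons of their retinal ganglion cells. Wild-type fish from a pet store had the eye muscles and the nerve severed, or the muscles alone in the sham operation, and RNA was pooled from eyes without lens and sclera at 3, 24 and 168 h. Each of the 9 arrays set 1 injured pool against 1 sham pool, 3 per time point. A further 2 arrays set pools of unoperated fish against each other, to see what differences arise without an operation. The labels name Cy5 for injured RNA on every array, but the array names give sham RNA in Cy5 on 6 of 9, and the values of the authors' deposited table follow the array names. All values are log2 of injured over sham in that orientation, with a standard error (SE) from 1 fit of all 9 arrays, which pools the spread over the time points. The labels call the pools biological replicates, so the p-values of single probes measure the spread between pools. Those of camera with its preset correlation compare a list with other genes, and do not measure how far a list varies between pools.

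On the control arrays the spread of log2 ratios over probes overlapped that on the injured-against-sham arrays. This spread includes dye effects and spots near the background, so it does not measure differences between pools alone. The log2 ratio had an SD over probes of 0.62 and 0.74 on the control arrays, and between 0.67 (24 h array 2) and 0.92 (168 h array 3) on the injured arrays. Probes beyond 2-fold made up 8.21% and 15.0% on the control arrays and 11.6% to 23.3% on the injured arrays. Dye gave the most calls: 1555 probes differed between Cy5 and Cy3 whatever the sample (353 higher in Cy5, 1202 lower, adjusted p under 0.05 in limma). Across probes, which are not independent replicates, the log ratios of arrays of the same time and dye orientation correlated at a mean r of 0.305 over 3 pairs, and injured arrays with control arrays, or the control arrays with each other, at 0.316 over 19 pairs. Spots above the empty positions made up 17.2% to 44.8% in Cy5 and 38.7% to 71.9% in Cy3 on the injured arrays, and 3306 probes were above that limit on all 9 of them.

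**Figure D1:**
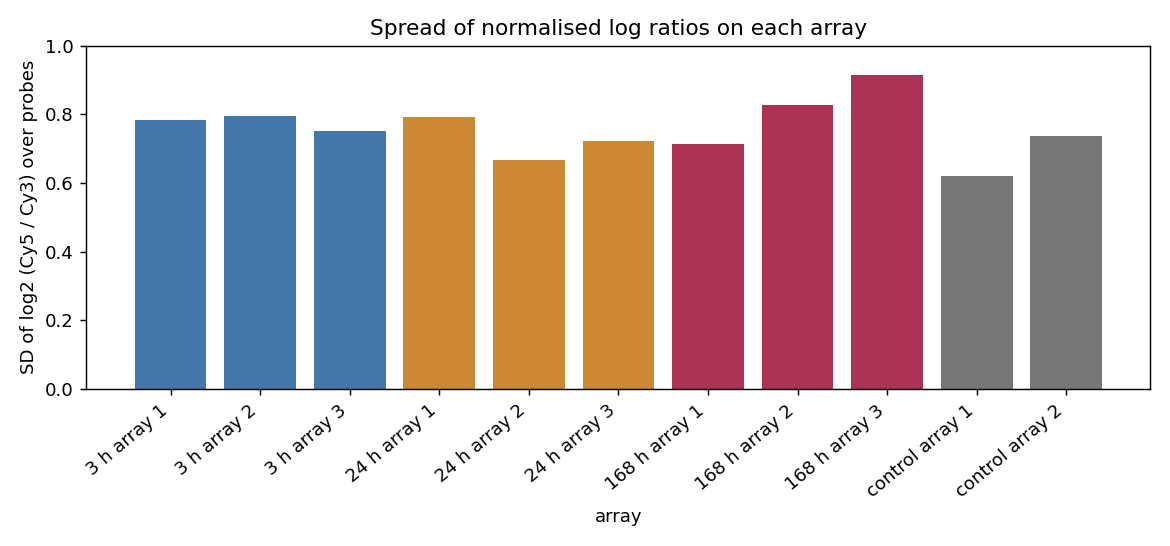
Bars show the SD over probes of the normalized log2 Cy5 over Cy3 ratio on each of the 11 arrays, starting at 0. The control arrays (0.62 and 0.74) lie close to the injured-against-sham arrays (0.67 to 0.92).

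At 3 h the lens list alone was called by camera with the preset correlation, although the lens had been removed from the sampled eyes. Of 13 measured lens genes 12 were tested, as cryaba had a spot marked bad, and their median was 0.55 with 10 of 12 above 0 (limma's camera, adjusted p = 9.1e-05; adjusted p = 0.482 with an estimated correlation). The crystallin gene crygs2 stood at 1.62 ± 0.49 (its other probe at -0.05), with 0.58, 3.50 and 0.79 on the 3 arrays and 0.68 without array 2. Its relative cryba4 stood at 0.82 ± 0.38 (2 of 3 arrays above 0), and at 0.32 without array 2 and 1.64 without array 3. The cryba4 probe was above the empty positions on 1 of 9 arrays, so its value lay near the background. The crystallin crygm2d1 was above the empty positions in the injured channel on 3 arrays and the lens connexin gja8b on 1, neither in any sham channel, so no fold is given. Of the 13 genes 2 passed when adjusted over the list alone, crygm2d1 and crygs2, and 0 over all probes, with 4 at an unadjusted p under 0.05 in limma. The medians of the 3 arrays were -0.04, 1.53 and 0.55, and without array 2 the list stood at 0.34 (adjusted p = 0.293), while without array 3 it stood at 1.06. The same genes had medians of 0.09 and 0.42 between unoperated pools.

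The immediate early genes, transcription factors and feedback regulators that respond first to a stimulus, had a 3 h median of 0.17 with 21 of 27 above 0, which did not pass in camera (adjusted p = 0.0857). Among them jun stood at 0.50 ± 0.31, egr1 at 0.21 ± 0.31 and fosab at -0.16 ± 0.35 (other probe 0.46). None of 14067 probes passed in limma at 3 h, with a smallest adjusted p of 0.9998. At an unadjusted p under 0.05 stood 630, fewer than expected with no effect. Among the named genes with the smallest p-values were hoxc1a, a homeobox gene (1.48 ± 0.31), and the cone phosphodiesterase pde6c (in the injured channel of 2 arrays and no sham channel, past the threshold when adjusted over the list alone). In the other direction stood the ephrin gene efna1a (-1.16 ± 0.32), the growth factor receptor pdgfra (in the sham channel of 2 arrays and no injured channel) and csad, which was above the empty positions in no channel at 3 h. None of these 5 passed over all probes. At 3 h efna1a was above the empty positions in 1 injured and 1 sham channel, and the authors' deposited table gives -0.065 for it and 0.52 for hoxc1a.

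At 24 h camera with the preset correlation called ribosomal protein and epithelial genes higher, and rod and cone genes lower by a small amount. None of these calls held with an estimated correlation. Ribosomal protein genes, which encode the parts of the ribosome, had a median of 0.39 with 67 of 71 above 0 (adjusted p = 4.06e-13; adjusted p = 0.482 with an estimated correlation). Epithelial and corneal genes had a median of 0.45 with 24 of 31 above 0 (adjusted p = 8.09e-05; adjusted p = 0.482 with an estimated correlation). Rod genes had a median of -0.24 with 15 of 19 below 0 (adjusted p = 0.0297; adjusted p = 0.693 with an estimated correlation). Cone genes had one of -0.24 with 18 of 21 below 0 (adjusted p = 0.0336; adjusted p = 0.596 with an estimated correlation). Between unoperated pools the medians were -0.23 and -0.39 for ribosomal, 0.03 and -0.53 for epithelial, 0.25 and 0.06 for rod and -0.01 and -0.10 for cone genes, where the sign has no meaning. Adjusted over the list alone, 0 members of these 4 lists passed at 24 h, with 3 ribosomal, 6 epithelial, 1 rod and 1 cone gene at an unadjusted p under 0.05 in limma.

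Single members at 24 h included the annexin anxa2a (1.2 ± 0.36), the keratins krt4 (1.18 ± 0.46) and krt97 (1.71 ± 0.74) and the tight junction gene cldn1 (0.71 ± 0.31). Ribosomal examples were rpl8 (0.69 ± 0.29), rps9 (0.65 ± 0.29), rplp1 (0.63 ± 0.31) and rpl5a (0.83 ± 0.37), and rpl8, rplp1 and rpl5a each had another probe below 0 (-0.19, -0.15 and -0.84). Without 24 h array 2 the values were 0.75 for anxa2a, 0.39 for krt4 and 0.69 for krt97, and without array 3 rpl5a stood at 1.36. In the rod list pde6a, a subunit of the rod phosphodiesterase, stood at -0.74 ± 0.30 (1 other probe at 0.25), pdcb (phosducin) at -0.65 ± 0.38, gnb1a at -0.56 ± 0.33 and rom1b at -0.55 ± 0.34. In the cone list guca1c stood at -0.81 ± 0.38, the arrestins arr3a and arr3b at -0.60 ± 0.39 and -0.53 ± 0.34, and the creatine kinase ckmt2b at -0.40 ± 0.34. Without 24 h array 3 guca1c stood at -1.29. At 24 h the authors' deposited table gives 0.32 for gnb1a, the opposite sign, 0.027 for rpl5a and -0.16 for rom1b. Without 24 h array 2, the array medians of which were 0.69 for epithelial and -0.72 for rod genes, the lists stood at 0.08 (epithelial, adjusted p = 0.391), -0.08 (rod, adjusted p = 0.468) and -0.16 (cone, adjusted p = 0.277), while the ribosomal list kept its call at 0.24. Without 24 h array 3 the medians were 0.61 (ribosomal), -0.53 (rod) and -0.46 (cone). The cone and rod calls were also lost without 24 h array 1 (adjusted p = 0.14 and 0.0786) and without 168 h array 2 (adjusted p = 0.0953 and 0.124).

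The smallest p-value at 24 h among named genes was that of atf3, a stress-induced transcription factor of injured neurons, at 2.01 ± 0.33 or 4.03-fold, with 2.22, 1.58 and 2.23 on the 3 arrays. It did not pass over all probes (adjusted p = 0.265) and passed when adjusted over the list alone, among both axon regeneration and immediate early genes. In limma 0 of 14065 probes passed at 24 h, with 703 at an unadjusted p under 0.05, the share expected with no effect. The next smallest p-values above 0 were those of the lysosomal protease ctsz (1.13 ± 0.31) and the tubulin tuba8l3 (1.09 ± 0.31, other probes -0.46 and 0.10), both with an adjusted p of 0.956. Below 0 stood the receptor phosphatase ptprub (-1.28 ± 0.30), the stress gene gadd45aa (in the sham channel of 2 arrays and no injured channel) and fech, an enzyme of haem synthesis that was above the empty positions in no channel. For gadd45aa the authors' deposited table gives 0.22.

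At 168 h camera with the preset correlation called rod and cone genes lower, ribosomal protein and proteasome genes higher, and 3 further lists shifted. With an estimated correlation all of these calls were lost. Rod genes, which serve phototransduction in dim light, had a median of -0.70 with 14 of 19 below 0 (adjusted p = 3.51e-06; adjusted p = 0.482 with an estimated correlation). Cone genes, their counterparts in bright light, had a median of -0.41 with 18 of 21 below 0 (adjusted p = 8.09e-05; adjusted p = 0.482 with an estimated correlation). Over all probes 0 passed, and 9 rod and 6 cone genes had an unadjusted p under 0.05 in limma. The rod gene rdh8b was above the empty positions in 1 sham and no injured channel. Adjusted over the list alone, 8 rod (rdh8b included) and 4 cone genes passed. The rod genes pdcb (-1.64 ± 0.38), pde6a (-1.54 ± 0.30; other probes -0.00, 0.18 and -0.44), gnb1a (-1.26 ± 0.33) and the rhodopsin kinase grk1b (-1.24 ± 0.33) were among them. So were the cone genes guca1c (-1.44 ± 0.38), gnb3b (-1.54 ± 0.49, 2 of 3 arrays below 0; 1 other probe at 0.03) and the blue and ultraviolet opsins opn1sw2 (-1.12 ± 0.32) and opn1sw1 (-1.19 ± 0.37, 2 of 3 arrays below 0). Rhodopsin itself, rho, stood at -0.74 ± 0.32, and its other 3 probes at -0.92, -1.23 and -0.91.

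The array medians at 168 h were -0.18, -1.09 and -0.71 for rod and 0.05, -0.72 and -0.65 for cone genes. Without 168 h array 2 the rod list stood at -0.33 (adjusted p = 0.195) and the cone list at -0.39 (adjusted p = 0.106), whereas without array 1 pdcb and gnb3b passed over all probes (adjusted p = 0.0456). Without array 1 gnb3b stood at -2.57 and opn1sw1 at -1.79, while without array 2 the values were -0.49 for guca1c, -0.55 for opn1sw2, -0.61 for gnb1a and -0.91 for gnb3b. Without array 3 gnb3b stood at -0.86, opn1sw1 at -0.72 and rho at -0.49. On 168 h array 2, 53.2% of the Arabidopsis probes were above the empty positions in Cy3, against 20.8% to 40.5% on the other injured arrays. Zebrafish probes too were above them in Cy3 most often there (71.9%, against 38.7% to 62.7%). Array 2 alone had injured RNA in Cy5 at 168 h. Between unoperated pools the rod medians were 0.25 and 0.06 and the cone medians -0.01 and -0.10. For gnb1a the authors' deposited table gives 0.48 at 168 h, against -1.36 for pdcb and -0.36 for pde6a.

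**Figure D2:**
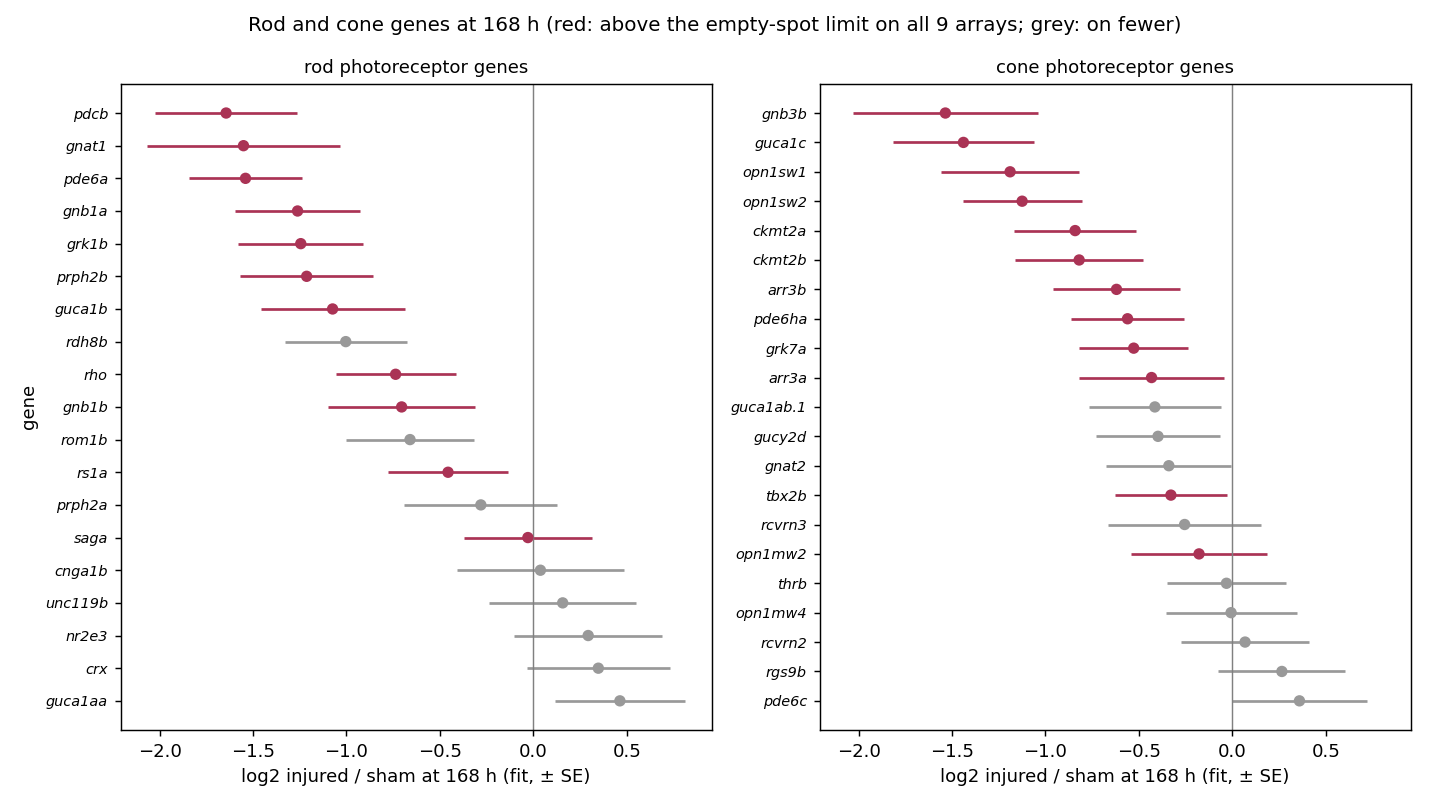
Points show the log2 of injured over sham at 168 h for the 19 rod and 21 cone genes, with bars of 1 SE from the fit of all 9 arrays, red where the probe was above the empty positions on all 9 arrays and grey otherwise. Below 0 lie 14 rod and 18 cone genes.

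Ribosomal protein genes had a median of 0.52 at 168 h with 67 of 71 above 0 (adjusted p = 2.61e-17; adjusted p = 0.482 with an estimated correlation), against -0.23 and -0.39 between unoperated pools. Among them rpl5b stood at 0.93 ± 0.31, rpl35 at 0.88 ± 0.30 and rps15 at 0.85 ± 0.29 (the list at 0.33 and rpl5b at 0.53 without 168 h array 2). Of the list 24 of 71 had an unadjusted p under 0.05 in limma, with 0 passing when adjusted over the list alone. For rps15 the authors' deposited table gives -0.01. Genes of the proteasome, which degrades tagged proteins, had a median of 0.31 with 33 of 40 above 0 (adjusted p = 0.00137; adjusted p = 0.482 with an estimated correlation). The subunits psmd10 (1.15 ± 0.39) and psma1 (0.80 ± 0.31) were examples, and psme2 was above the empty positions in 1 injured and no sham channel. Another subunit, psmd12, stood at -0.82 ± 0.34 (other probes 0.01, -0.15, 0.57 and 0.31). Of these genes 0 of 40 passed when adjusted over the list alone, with 6 at an unadjusted p under 0.05 in limma. Without 168 h array 2 the proteasome list stood at 0.20 (adjusted p = 0.263). Its medians between unoperated pools were -0.16 and 0.23.

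Oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, had a median of -0.30 with 35 of 49 below 0 (adjusted p = 0.00254; adjusted p = 0.482 with an estimated correlation). Members were ndufs1 (-1.13 ± 0.31), atp5f1d (-1.53 ± 0.52, 2 of 3 arrays below 0) and atp5po (-0.62 ± 0.30; other probes 0.21 and 0.19), whereas cox6b1 stood at 1.51 ± 0.32 and was the 1 member that passed when adjusted over the list alone. Leukocyte and microglia genes had a median of 0.20 with 18 of 26 above 0 (adjusted p = 0.0386; adjusted p = 0.482 with an estimated correlation). Examples were the granulin grna.2 (1.32 ± 0.32), which alone passed when adjusted over the list alone, lysozyme lyz (1.19 ± 0.44), apoeb (0.85 ± 0.32) and mhc1uba (0.75 ± 0.32). The lyz probe was above the empty positions on 1 of 9 arrays, so its value lay near the background. For grna.2 at 168 h the authors' deposited table gives 0.44. Epithelial and corneal genes had a median of 0.36 with 24 of 31 above 0 (adjusted p = 0.0386; adjusted p = 0.676 with an estimated correlation). Here anxa2a (1.40 ± 0.36) alone passed when adjusted over the list alone, krt8 stood at 0.79 ± 0.33 (1 other probe at -0.14) and anxa1a at 0.79 ± 0.38 (other probes -0.13 and 0.32), and cdh17 was above the empty positions in no channel. Without 168 h array 2 the oxidative phosphorylation list stood at -0.25 (adjusted p = 0.162) and the leukocyte list at 0.34 (adjusted p = 0.444), and without array 3 they stood at -0.27 (adjusted p = 0.103) and 0.10. Of their genes, without array 2 grna.2 stood at 0.82, lyz at -0.07, apoeb at 0.44, mhc1uba at 0.46 and cox6b1 at 1.00, and without array 3 atp5f1d stood at -0.45. The epithelial genes krt8 and anxa1a stood at 0.49 without array 1 and 0.47 without array 3. The leukocyte call was also lost without 168 h array 1 (0.28, adjusted p = 0.138). The epithelial list stood at 0.55 without 168 h array 2, and its call was lost without 168 h array 1 (0.20, adjusted p = 0.478) or 3 (0.23, adjusted p = 0.147) and without 3 h array 2 (0.33, adjusted p = 0.0555) or 3 (0.25, adjusted p = 0.108). Between unoperated pools the medians were -0.04 and 0.03 for oxidative phosphorylation, -0.31 and -0.25 for leukocyte and 0.03 and -0.53 for epithelial genes.

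The smallest p-value at 168 h was that of tubb5, a beta tubulin of growing neurons, at 2.31 ± 0.33 or 4.95-fold, with 1.91, 2.46 and 2.55 on the 3 arrays. It came close to the threshold over all probes (adjusted p = 0.0683) and passed when adjusted over the list alone, while its other probes stood at 0.78, -0.26 and 0.40. In limma 0 of 14065 probes passed at 168 h, with 1101 at an unadjusted p under 0.05. Without 3 h array 2, tubb5 passed (adjusted p = 0.0307), and it did so without 168 h array 1 (adjusted p = 0.0456). The growth factor gene fgf24 stood at 1.44 ± 0.32, atf3 at 1.2 ± 0.33 and tuba8l3 at 1.34 ± 0.31 (1 other probe at -0.17). Below 0 stood arl3l2 (-1.62 ± 0.34) and cnn2, a calponin (-1.47 ± 0.32). Beside these, tubb5, atf3 and tuba8l3 have values of 1.81, 1.09 and 1.09 at 168 h in the authors' deposited table.

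On average over the 3 times, camera with the preset correlation called ribosomal protein genes higher and rod genes lower. Neither call held with an estimated correlation. The ribosomal list had a median of 0.32 with 69 of 71 above 0 (adjusted p = 1.18e-18; adjusted p = 0.482 with an estimated correlation). Among them stood rpl5a at 0.74 ± 0.22 (1 other probe at -0.56) and rpl8 at 0.51 ± 0.17 (2 other probes at -0.19 and -0.13). For rpl5a the authors' deposited table gives 0.19, 0.027 and -0.11 at the 3 times. The rod list had a median of -0.41 with 16 of 19 below 0 (adjusted p = 9.39e-06; adjusted p = 0.482 with an estimated correlation). Here pdcb stood at -0.83 ± 0.23, pde6a at -0.80 ± 0.18 (1 other probe at 0.11), gnb1a at -0.71 ± 0.20 and grk1b at -0.65 ± 0.20. At the 3 times the authors' deposited table gives -0.11, 0.32 and 0.48 for gnb1a and 0.15, -0.37 and -0.36 for pde6a. Cone genes had a median of -0.22 with 19 of 21 below 0 (adjusted p = 0.000705; adjusted p = 0.482 with an estimated correlation). Among them stood guca1c at -0.82 ± 0.23, gnb3b at -0.71 ± 0.30, opn1sw1 at -0.56 ± 0.22 and, in the other direction, pde6c at 0.55 ± 0.22. Without 168 h array 2 the average was -0.42 for guca1c, -0.44 for gnb3b and -0.43 for gnb1a. Epithelial genes had one of 0.24 with 24 of 31 above 0 (adjusted p = 0.00136; adjusted p = 0.53 with an estimated correlation). Among them stood anxa2a at 0.84 ± 0.22, krt5 at 0.68 ± 0.35, krt8 at 0.53 ± 0.20 (1 other probe at -0.05) and anxa1a at 0.46 ± 0.23. For krt5 the authors' deposited table gives 0.04, -0.13 and -0.09 at the 3 times. Proteasome genes had one of 0.20 with 31 of 40 above 0 (adjusted p = 0.00382; adjusted p = 0.482 with an estimated correlation). Among them stood psmd6 at 0.57 ± 0.20 (other probe -0.07), psme2 at 0.43 ± 0.18, psmb2 at 0.40 ± 0.19 (other probe -0.17) and psmd4a at -0.41 ± 0.18 (other probes 0.66 and 0.26). For psme2 the authors' deposited table gives 0.11, -0.21 and 0.22. Oxidative phosphorylation genes had one of -0.16 with 37 of 49 below 0 (adjusted p = 0.00913; adjusted p = 0.482 with an estimated correlation). Among them stood sdha at -0.53 ± 0.23 (other probe 0.01), ndufs1 at -0.45 ± 0.19, ndufb9 at -0.41 ± 0.18 (other probe 0.06) and cox6b1 at 0.79 ± 0.19. Adjusted over the list alone, 4 rod, 1 epithelial and 1 oxidative phosphorylation gene passed and 0 of the ribosomal, cone and proteasome genes.

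In limma 0 of 14065 probes passed on average, with 1054 at an unadjusted p under 0.05, and 0 passed for a difference at any time, with 787. The smallest p-values belonged to atf3 (1.09 ± 0.20, 8 of 9 arrays above 0, adjusted p = 0.406), tuba8l3 (0.95 ± 0.19, 9 of 9; 1 other probe at -0.21) and the transcription factor yy1a (1.04 ± 0.22, 9 of 9; 2 of 5 other probes below 0, at -0.01 and -0.24). For yy1a the authors' deposited table gives 0.30, 0.40 and -0.11 at 3, 24 and 168 h. Below 0 stood, beside pde6a, stxbp6 and the DNA repair gene rad51d, above the empty positions in 2 and 4 sham channels and no injured channel. An exact two-sided permutation of the dye orientations within time points (27 arrangements) gave p = 0.037 for the mean of the ribosomal, rod, proteasome and oxidative phosphorylation lists, the smallest it can give, and an adjusted p of 0.148 over the 28 lists. The extracellular matrix, skeletal muscle and unfolded protein lists, which camera did not call, reached the same exact p. For epithelial genes this exact p was 0.0741 and for cone genes 0.111. Without 3 h array 3 the epithelial list stood at 0.08 (adjusted p = 0.646). Without 168 h array 2 the average calls of rod (-0.17, adjusted p = 0.0952), cone (-0.19, adjusted p = 0.0953), proteasome (0.17, adjusted p = 0.194) and oxidative phosphorylation genes (-0.13, adjusted p = 0.137) were lost, the last also without 24 h array 3 (-0.19, adjusted p = 0.0518).

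**Figure D3:**
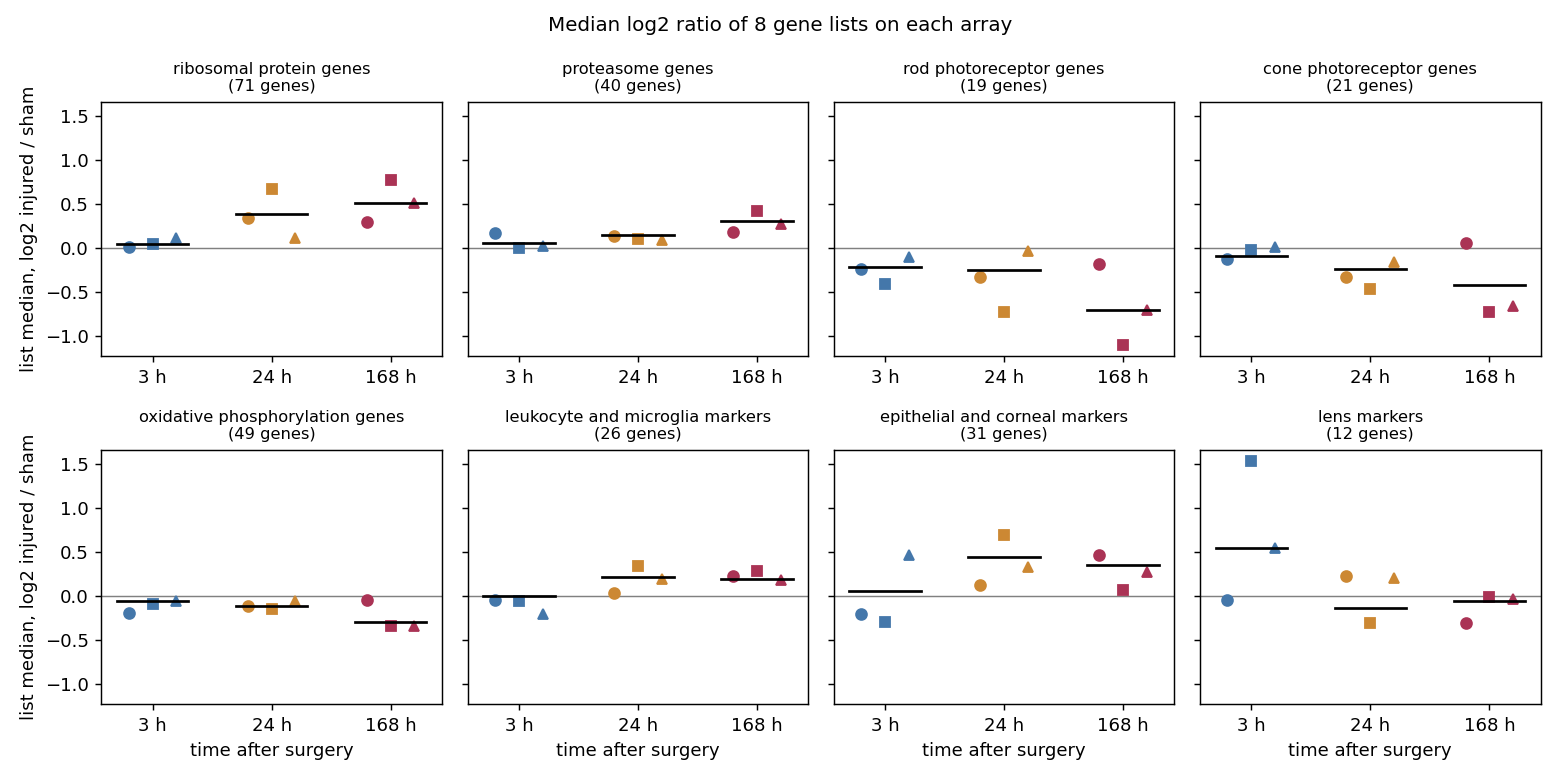
Each panel shows 1 gene list, with time after surgery on the horizontal axis and the list's median log2 of injured over sham on the vertical axis. Circles, squares and triangles are arrays 1, 2 and 3 of a time point and black bars the fitted median, which for rod genes is -0.24 at 24 h and -0.70 at 168 h.

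Set against each other, the time points differed in photoreceptor, ribosomal, lens and epithelial genes in camera with the preset correlation. With an estimated correlation 0 of these differences were called. From 3 h to 168 h the injury effect fell in rod genes (-0.64, 14 of 19 below 0, adjusted p = 0.00354) and cone genes (-0.63, 17 of 21 below 0, adjusted p = 0.00318), and rose in ribosomal protein genes (0.44, 68 of 71 above 0, adjusted p = 4.87e-09). Lens genes were lower by then (-0.63, 10 of 12 below 0, adjusted p = 0.00815). These 4 differences each had an adjusted p = 0.93 with an estimated correlation. From 3 h to 24 h ribosomal protein genes rose (0.33, 63 of 71 above 0, adjusted p = 1.93e-05; adjusted p = 0.96 with an estimated correlation). Epithelial genes rose too (0.28, 24 of 31 above 0, adjusted p = 0.00815), and lens genes fell (-0.40, 8 of 12 below 0, adjusted p = 0.0198), each with an adjusted p = 0.93 with an estimated correlation. From 24 h to 168 h rod genes fell (-0.43, 14 of 19 below 0, adjusted p = 0.042; adjusted p = 0.96 with an estimated correlation). In limma 0 probes passed for any of the 3 differences, with 590 (24 h against 3 h), 603 (168 h against 24 h) and 707 (168 h against 3 h) at an unadjusted p under 0.05. The counts of 590 and 603 lay below the share expected with no effect, and 707 lay close to it. Adjusted over the list alone, members of lists without a shift passed: 1 axon regeneration and 1 immediate early gene for 24 h against 3 h, and 1 cytoskeleton, 2 erythrocyte and 1 ganglion cell gene for 168 h against 24 h. For 168 h against 3 h, 1 cytoskeleton, 1 ganglion cell and 1 pigment epithelium gene passed in this way.

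Genes known from axon regrowth did not pass as a group in camera: the axon regeneration list of 36 genes had medians of 0.05, -0.03 and 0.12 at 3, 24 and 168 h (adjusted p = 0.389 at 168 h). In fry's test of change in either direction it passed at 24 h (adjusted p = 0.000113) and on average (adjusted p = 0.00011). The cytokine signalling inhibitor socs3a stood at 0.69 ± 0.31, 0.48 ± 0.31 and 0.39 ± 0.31 at the 3 times and the protease mmp9 at 0.58 ± 0.31, 0.31 ± 0.31 and 0.51 ± 0.31 (1 other probe at -0.18 at 24 h), both above 0 on 9 of 9 arrays. The proneural factor ascl1a stood at 0.60 ± 0.41, 0.97 ± 0.41 and 0.40 ± 0.41, and the replication gene pcna at -0.08 ± 0.36, 0.39 ± 0.36 and 0.95 ± 0.36. The tubulin tuba1b stood at 0.62 ± 0.53, -0.42 ± 0.53 and 0.64 ± 0.53 and the adhesion gene alcama at 0.53 ± 0.35, -0.37 ± 0.35 and 0.80 ± 0.35. Without 3 h array 1 or 3 the 3 h value of tuba1b was -0.13 or 2.05, and without 24 h array 1 or 3 its 24 h value was 0.28 or -1.66. The authors' deposited table gives 0.20 for tuba1b at 3 h, and 0.03 and -0.03 for alcama at 3 h and 168 h. The ganglion cell factor isl2b stood at -1.21 ± 0.39 at 24 h (other probe -0.84), against -0.46 ± 0.39 at 3 h and 0.07 ± 0.39 at 168 h (other probe 0.07 and -0.31). Without 24 h array 3 isl2b stood at -0.39 at 24 h, and without array 2 ascl1a stood at 0.58. At 168 h alcama was at 0.42 without array 1 and pcna at 0.61 without array 3. Average values were 0.37 ± 0.19 for jun, 0.25 ± 0.20 for sox11b, 0.08 ± 0.19 for sox11a, 0.11 ± 0.17 for klf6a. They were -0.02 ± 0.19 for egr1, -0.58 ± 0.22 for stat3 (other probe 0.80), -0.10 ± 0.21 for fosab (other probe 0.14) and -0.13 ± 0.26 for c3a.1. The growth cone gene gap43 was above the empty positions in 1 injured channel at 24 h and 1 sham channel at 168 h, so no fold is given. The brighter probe of the glial filament gene gfap was above the empty positions at 3 h alone (0.07 ± 0.42). The other, above them on 5 arrays, stood at -0.30, -0.04 and 0.38 at the 3 times. None of these genes passed over all probes.

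**Figure D4:**
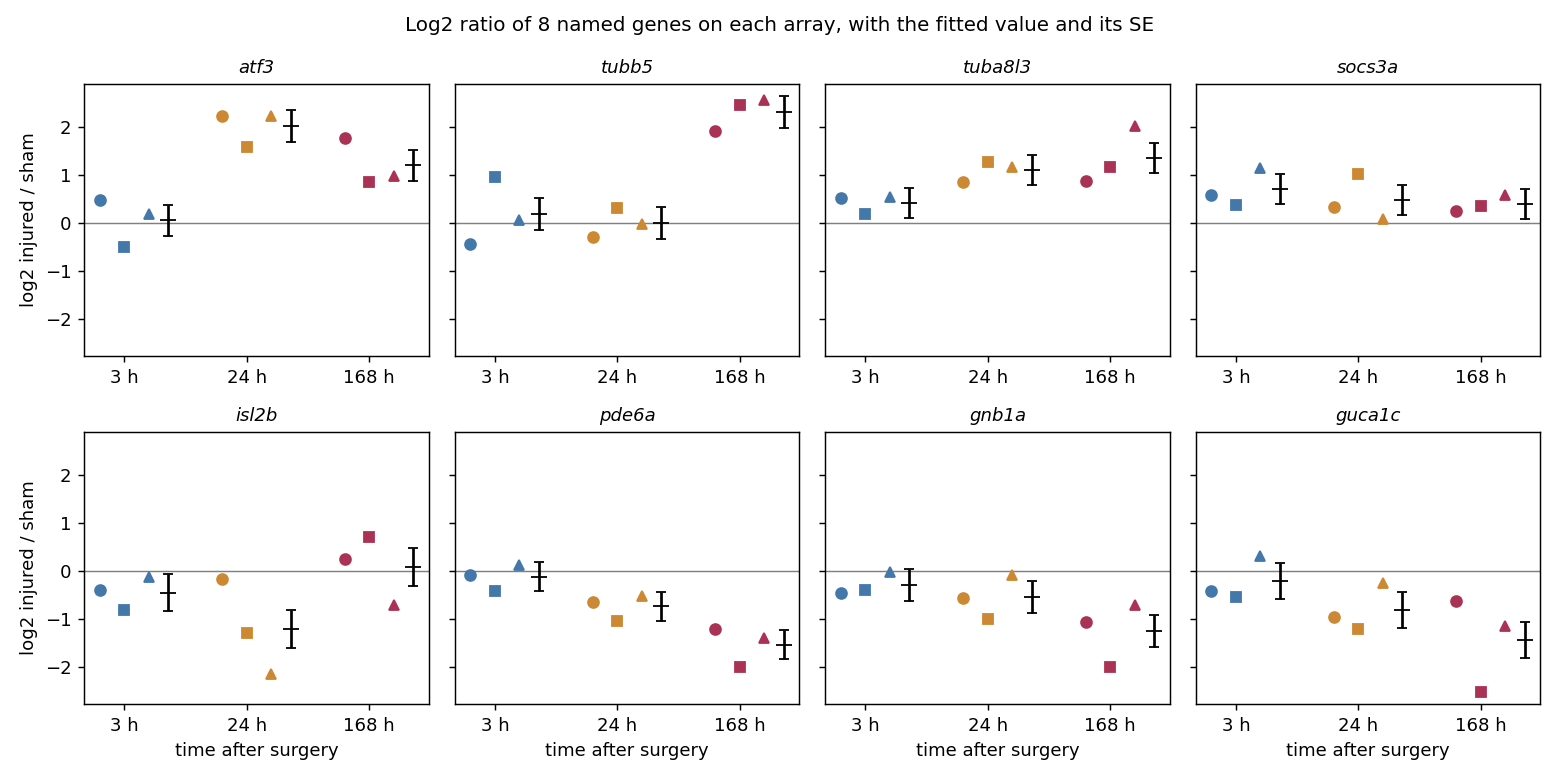
Each panel shows 1 gene, with time after surgery on the horizontal axis and log2 of injured over sham on the vertical axis, as points for the 3 arrays and a fitted value with a bar of 1 SE. The fitted value of atf3 is 0.05 at 3 h, 2.01 at 24 h and 1.2 at 168 h, and that of tubb5 is 2.31 at 168 h.

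The remaining lists passed at no time and not on average in camera or in fry's test of a common direction. Markers of other retinal cells had 168 h medians of 0.07 for ganglion cells (28 genes, adjusted p = 0.619), 0.02 for Müller glia and astrocytes (29 genes, adjusted p = 0.663) and -0.05 for inner retinal neurons (29 genes, adjusted p = 0.774). Markers of tissue near the retina gave 0.06 for pigment epithelium (17 genes, adjusted p = 0.503), 0.14 for skeletal muscle (42 genes, adjusted p = 0.281) and -0.10 for erythrocytes (15 genes, adjusted p = 0.224). At 168 h inflammation and stress lists gave 0.16 for cytokines (14 genes, adjusted p = 0.91), -0.09 for complement (17 genes, adjusted p = 0.782). They gave -0.04 for JAK-STAT signalling (15 genes, adjusted p = 0.959), 0.01 for heat shock genes (31 genes, adjusted p = 0.982) and 0.03 for unfolded protein and oxidative stress genes (34 genes, adjusted p = 0.745). Cell cycle genes stood at 0.10 (54 genes, adjusted p = 0.665), cytoskeleton at 0.02 (63 genes, adjusted p = 0.32), extracellular matrix at 0.07 (36 genes, adjusted p = 0.418). The others were apoptosis at -0.08 (32 genes, adjusted p = 0.979), hypoxia and glycolysis at -0.01 (34 genes, adjusted p = 0.782), circadian clock at -0.04 (27 genes, adjusted p = 0.588) and sterol and lipid genes at 0.13 (37 genes, adjusted p = 0.782). Of the 112 tests of lists at the 3 times and on average, 18 passed in camera with the preset correlation, 0 with an estimated correlation and 0 in fry's test of a common direction. In fry's test of change in either direction 19 passed, among them sterol and lipid, cytoskeleton and ganglion cell genes at 168 h.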

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

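The tests of a dye effect that differed between times, of the share of photoreceptor RNA, of lens tissue in 1 pool and of differences between unoperated pools were chosen after the results had been seen, and so was the bound of 0.5% of random sets, which is stricter than the central 95% written down for the dye and lens tests. The intensity tests and the splits of the arrays were set before. Lists stand here because their injury effect differed between time points by a test of the difference itself: epithelial (0.28), lens (-0.40) and ribosomal protein genes (0.33) from 3 h to 24 h, rod genes (-0.43) from 24 h to 168 h, and cone (-0.63), lens (-0.63), ribosomal protein (0.44) and rod genes (-0.64) from 3 h to 168 h. All 8 passed with the preset correlation and 0 with an estimated one (adjusted p = 0.93 or 0.96). For 168 h against 3 h, 4 lists differed and the highest of the other splits of the 6 arrays gave 3. For 24 h against 3 h the counts were 3 and 2, and for 168 h against 24 h 1 and 4 (8 of 10 splits with at least 1), and 10 splits are too few for a share under 0.05.

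Data outside the comparisons also held signals. The control column of the authors' deposited table holds 1 repeated value in 3573 lines, and its other values do not follow either control array (r = 0.026 and 0.0556 across probes, while the control arrays correlate at 0.388 with each other). On control array 1, 54.3% of the Arabidopsis probes exceeded the empty positions in Cy3 and 8.09% in Cy5. In Cy3 the share was 50.3% on control array 2 and 53.2% on 168 h array 2, against 20.8% to 40.5% on the other injured arrays. Zebrafish probes exceeded the empty positions in Cy3 most often on the same arrays. Their share was 68.6% on each control array and 71.9% on 168 h array 2, against 38.7% to 62.7% on the other injured arrays. Without 168 h array 2, which alone had injured RNA in Cy5 at that time, the lists passing fell from 18 to 7.

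Rod and cone genes were lower at 168 h, with a median of -0.49 over 40 genes. Of 10000 random gene sets of similar intensity 0 reached it (0.01% with the real set counted), which argues against an intensity-dependent bias of the list as a whole. Random sets were matched by ranges of intensity rank, so they say little on the brightest genes, such as rho. The rod and cone median was -0.81 with injured RNA in Cy5 and -0.31 with it in Cy3 (0.22% of random sets as low). Both lay below 0, which a dye effect that differed at 168 h does not give alone. That effect still cannot be told apart, since the sign in Cy5 rests on 1 array. A smaller share of photoreceptor RNA also stays open, as the other 3 retinal lists lay between -0.053 and 0.074. Loss of expression per photoreceptor after injury is a further candidate explanation that was not tested.

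Ribosomal protein genes were higher at 24 h and 168 h, with a median of 0.47. Of 10000 random sets of the same intensity 0 reached it (0.01% with the real set counted), which argues against intensity bias. A dye effect that differed at these times cannot be told apart: both orientations lay above 0 (0.42 for the one nearer 0, that of Cy5), but of the 2 arrays with injured RNA in Cy5 only 168 h array 2 was beyond random sets (0.77), and 5.15% of them were as high as 24 h array 3 (0.11). A difference between pools that arises without injury stays open, because unoperated pools differed by -0.23 and -0.39. The 2 control arrays share 1 pool, so their values are not independent. Each is the median of 1 array, whereas 0.47 comes from the fit over all injured arrays. On both control arrays the list also lay beyond its random sets (0.01% as low, with the real set counted). The comparison with random sets therefore does not single out injury. Injury itself may account for the shift, a hypothesis these arrays cannot separate from differences between pools or dyes.

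Lens genes were higher at 3 h. Of 10000 random sets of the same intensity 0 reached that median (0.01% with the real set counted), which argues against an intensity bias. Lens tissue left in 1 injured pool is a candidate explanation that stays open: array 2 had a median of 1.53, and the other 2 arrays together gave 0.34. This lay above the central 95% of random sets of the same intensity (up to 0.30, and 1.24% were as high), which counts against 1 pool as the whole source, but it rested on array 3 (0.55, against -0.04 on array 1). No biological explanation was tested for this pattern.

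Other arrangements of the injured and sham labels bear on the counts. On average over times 1054 probes had an unadjusted p under 0.05 and another of the 27 arrangements gave 1082 (2 of 27 as large), at any time 787 against 883 (8 of 27), and for lists 6 against 8 (5 of 27), so chance cannot be excluded for any of the 3. The single times allow 3 arrangements and the differences between times 10 splits, too few for a share under 0.05. Real and highest other counts of probes were 630 and 738 at 3 h (3 of 3 as large), 703 and 643 at 24 h (1 of 3), 1101 and 1050 at 168 h (1 of 3), 590 and 770 for 24 h against 3 h (9 of 10), 603 and 935 for 168 h against 24 h (8 of 10), and 707 and 921 for 168 h against 3 h (5 of 10). With the labels of the other times rearranged as well, the highest of 27 arrangements were 780 at 3 h, 710 at 24 h and 1130 at 168 h, each above the real count. Counts of lists were 1 and 1 at 3 h (2 of 3), 4 and 3 at 24 h (1 of 3) and 7 and 4 at 168 h (1 of 3).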

How the results depend on the processing

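Joint omission of 2 arrays and foreground medians were tests chosen after the results had been seen. Causes were not tested unless stated.

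Taking Cy5 as injured on every array, as the labels read, leaves the dye effect inside the injury effect by construction. It also reverses 6 of the 9 arrays, so effects in the main orientation shrink or change sign by construction. Probes passing were then 387 (3 h), 200 (24 h), 401 (168 h), 1863 (average) and 832 (any time), with 0 lists. List medians became -0.86 (lens, 3 h); at 24 h 0.14 (cone), -0.14 (epithelial), -0.093 (ribosomal) and 0.13 (rod); at 168 h 0.027 (cone), -0.15 (epithelial), -0.17 (leukocyte), 0.087 (oxidative phosphorylation), 0.011 (proteasome), 0.10 (ribosomal) and -0.082 (rod). On average they were 0.052 (cone), 0.15 (epithelial), 0.10 (oxidative phosphorylation), -0.016 (proteasome), 0.082 (ribosomal) and -0.050 (rod). Of 167 gene values 102 changed sign. Among them atf3 turned to -0.50 (24 h) and tubb5 to -0.59 (168 h). The value of anxa1a turned to -1.64 (168 h) and -1.18 (average), that of pde6c to -0.87 (average) and that of psmd6 to -0.80 (average). Further values were -1.81 for tuba1b (3 h), -1.33 (168 h) and -1.01 (average) for mmp9 and -0.83 for jun (average). For gnb1a at 168 h the authors' deposited table has 0.48, while own settings without the dye term or background subtraction gave -1.23 and -1.30. Over the other 24 settings 129 gene values never changed sign and 38 did in at least 1.

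With no background subtraction 6 probes passed at 168 h (4 higher, 2 lower; tubb5 and pde6a among them) and 1 on average, and epithelial genes at 168 h lost their call (0.18). With an offset of 0 cone (-0.25) and rod genes (-0.28) at 24 h and leukocyte genes (0.30) lost theirs. Median centring gave 1 probe at 168 h, 1 on average and 2679 with a dye effect, and ended the calls of cone (-0.15) and rod (-0.12) at 24 h, oxidative phosphorylation at 168 h (-0.057) and on average (-0.020), and cone on average (-0.17). Print-tip loess ended those of rod at 24 h (-0.22) and leukocyte genes (0.15). The brighter probes alone ended epithelial (0.36) and leukocyte (0.20) calls at 168 h, and added control arrays did the same (0.31 and 0.17). With no dye term cone (-0.27) and rod (-0.25) at 24 h and epithelial (0.22) and leukocyte (0.34) at 168 h lost their calls. Each time alone gave 11 lists, without epithelial at 168 h (0.22). A threshold of 0.1 gave 1 probe at 168 h and 2515 with a dye effect. Foreground medians gave 1 probe at 168 h and ended the leukocyte call (0.15). Without 3 h array 2 and 24 h array 2 together, lens at 3 h (0.34) and cone (-0.16), epithelial (0.077) and rod (-0.082) at 24 h lost theirs.

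An estimated correlation and fry each left 0 of the 18 list calls, at unchanged medians: lens 0.55 (3 h); cone -0.24, epithelial 0.45, ribosomal 0.39 and rod -0.24 (24 h); cone -0.41, epithelial 0.36, leukocyte 0.20, oxidative phosphorylation -0.30, proteasome 0.31, ribosomal 0.52 and rod -0.70 (168 h); cone -0.22, epithelial 0.24, oxidative phosphorylation -0.16, proteasome 0.20, ribosomal 0.32 and rod -0.41 (average).

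Leaving out 1 array in turn, the lone array of a dye orientation included, gave medians of 0.34 to 1.06 (lens, 3 h); -0.46 to -0.16 (cone), 0.077 to 0.66 (epithelial), 0.24 to 0.61 (ribosomal) and -0.53 to -0.082 (rod) at 24 h; -0.58 to -0.37 (cone), 0.20 to 0.55 (epithelial), 0.10 to 0.34 (leukocyte), -0.39 to -0.25 (oxidative phosphorylation), 0.20 to 0.36 (proteasome), 0.33 to 0.62 (ribosomal) and -0.98 to -0.33 (rod) at 168 h; and -0.33 to -0.18 (cone), 0.084 to 0.31 (epithelial), -0.19 to -0.13 (oxidative phosphorylation), 0.16 to 0.22 (proteasome), 0.25 to 0.44 (ribosomal) and -0.48 to -0.17 (rod) on average. Ribosomal calls with the preset correlation held in all 9. That test is too liberal for lists whose members vary together, so this does not show that the shift exceeds differences between pools. Of the 167 gene values 97 moved more than 1.5-fold or changed sign when some 1 array was left out. Probes passing were 0 to 10 at 168 h (10 without array 1 of that time) and 673 to 1433 for dye, and lists 7 to 19.

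The SD on the control arrays was 0.51 and 0.49 without background subtraction and 0.74 among the brighter probes of array 1. Aquantile scaling leaves log ratios unchanged by construction. A batch term was not run.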

Other observations

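The genes and lists here were picked after their values had been seen, apart from the lists themselves. A few genes passed within lists that did not shift. At 168 h the visual cycle enzyme rpe65a was at 1.61 ± 0.40 and passed when adjusted over the list alone (adjusted p = 0.019), with other probes at 0.24 and 0.70. At 3 h its 3 probes stood at -1.09, -0.56 and -1.12, and the average over times was 0.27 ± 0.24. In the sterol and lipid list at 168 h elovl4b (-1.16 ± 0.34) and fabp3 (1.11 ± 0.30) were among 4 genes that passed when adjusted over the list alone, in opposite directions. At the same time the haemoglobin gene hbba2 stood at -1.37 ± 0.38 and the chaperone fkbp5 at -1.54 ± 0.40, and both passed in their lists (adjusted p = 0.0252 and 0.0477). On average over times the collagen gene col1a1a stood at 0.89 ± 0.21 (adjusted p = 0.0231 over its list), while its other probes were at -0.01 and 0.06. None of these genes passed over all probes.

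In fry's test of change in either direction, which does not compare a list with other genes, 19 of 112 tests passed. Among them were axon regeneration genes at 24 h (adjusted p = 0.000113, median -0.03, 17 of 36 above 0), and at 168 h sterol and lipid genes (adjusted p = 7.78e-06, median 0.13, 21 of 37 above 0), cytoskeleton genes (adjusted p = 0.00011, median 0.02, 33 of 63 above 0) and ganglion cell genes (adjusted p = 0.000857, median 0.07, 17 of 28 above 0). The axon regeneration list holds atf3, and the last pair of lists share tubb5.

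Effects at different times correlated across probes at r = 0.0837 (3 h with 24 h), 0.186 (24 h with 168 h) and 0.111 (3 h with 168 h). Data simulated with no injury effect gave 0.0355, 0.0417 and 0.0319, since the times share 1 dye estimate. Probes are not independent replicates.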
